A study of Oryza sativa with 8 samples.

How the data were processed

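Total RNA of whole rice seedlings, extracted with a Sigma Spectrum kit, was labelled with Cy3 by a kit that primes cDNA with oligo dT and makes cRNA by in vitro transcription, per the labels. The 8 arrays formed 4 groups of 2: the high type (AC39020) and the low type (BPT5204), each under control conditions and under stress. All 8 arrays lay on 1 slide and were scanned in 1 scan. The high type filled slide row 1 and the low type row 2, with control arrays in columns 1 and 2 and stress arrays in columns 3 and 4, so type cannot be separated from row nor treatment from column. Nothing in the labels states that replicates came from separate cultures, so the p-values measure the spread between these samples.

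Per the file headers the authors extracted the scans with Agilent Feature Extraction 11.5.1.1, and the processed signal is an intensity after background subtraction and detrending, with low values replaced by surrogates and no scaling between arrays. The raw spot means and local backgrounds in the deposited scanner files are intensities too, and the flag columns are other values of that software (well above background, saturated, outlier spot), per the file headers. The deposited value table holds log2 values. Set against the log2 processed signal of the same array, its values differed by a constant per array to within 0.001 for 99.92% to 99.99% of single-spot probes, and 59923 of 59925 probes were matched. The constants were 10.7362 and 10.8337 (high-type control), 10.5138 and 10.6963 (high-type stress), 10.5851 and 10.5284 (low-type control) and 9.6578 and 10.1628 (low-type stress). The column medians were −3.0944, −3.0857, −3.1939, −3.0027, −3.2498, −3.3007, −2.9223 and −3.0495 in the same order, with the 75th percentile of each column at 0 to within 0.01.

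The main analysis started from the processed signal of the 61657 non-control spots. Outlier spots flagged by the software were removed (68 genes had at least 1), no spot was saturated, log2 values of replicate spots were averaged, and the 75th percentile of each array was subtracted. Signal over local background at the 75th percentile was 82.8, 83.4, 70.2, 78.0, 77.3, 72.0, 41.9 and 57.1 in the same order of arrays. Genes were taken from the annotation on the array. Of 59925 probes, 53321 carried a single locus of the Rice Annotation Project (RAP), 1021 several and 5583 none, and probes without a single locus were left out of the gene tests and counted apart. The supplied table of locus tags matched 1 RAP locus, so symbols come from the array annotation and from common rice names. The files give no coordinates for the probes, so a chromosome is known from the locus number alone. The brightest probe stood for each gene (30119 of 38028 genes had 1 probe), and a gene was tested when that probe was well above background on both arrays of at least 1 group, which left 27329 genes.

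A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3, with 4 residual degrees of freedom and an empirical Bayes prior of 1.83 degrees of freedom and a standard deviation of 0.166 (log2). The comparisons were stress against control in each type, the difference of these changes (high type minus low type), and high type over low type under control and under stress. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all tested genes of a comparison, and 0.05 was the threshold. The median gene changed by −0.03, 0.16, −0.15, −0.06 and −0.14 (log2) in the 5 comparisons in that order, and under quantile scaling by −0.024, 0.025, −0.033, −0.059 and −0.073. Changes in the text are therefore relative to that median, except bounds written as at least N-fold. Those are given for genes well above background on both arrays of 1 group and on neither array of the other, and on each array of that other group the gene was set to its own signal or to the lowest signal well above background on the array, whichever was higher. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 did the rest. Replicates correlated at 0.995, 0.973, 0.991 and 0.985 with a pooled standard deviation of 0.225, 0.523, 0.306 and 0.387 (log2) for high-type control, high-type stress, low-type control and low-type stress. On arrays simulated with the fitted spread of each gene, 0 of 67 changes of 0.585 log2 units, 10.4% of 1 unit and 80.3% of 2 units were called. Of 62 calls 2 were false. Far fewer genes were changed there than were called in the data, and all groups shared 1 spread per gene. These shares therefore do not give the sensitivity or the rate of false calls of the comparisons here.

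The gene lists as first written, the groups, the comparisons, the alternatives and the rule for named genes were chosen before the data were examined. Lists were drawn from annotation words and tested against all other tested genes with camera in limma at a preset correlation of 0.01, for lists of at least 4 tested genes, with adjustment over the lists of a comparison, and again with a correlation estimated from the data. With that estimate no list was called in any of the 5 comparisons. They cover the removal of reactive oxygen and carbonyls (antioxidant enzymes, glutathione S-transferases, class III peroxidases, thioredoxins and glutaredoxins, aldehyde and carbonyl detoxification), its source (respiratory burst oxidases), protein folding (small heat shock proteins, chaperones, heat stress transcription factors), and water loss (LEA proteins and dehydrins, protein phosphatases 2C, abscisic acid synthesis and breakdown, osmolyte synthesis, aquaporins). Others are transcription factor families (AP2/ERF and DREB, NAC, WRKY, bZIP, MYB), jasmonate synthesis and JAZ repressors, defence proteins, light harvesting and photosystem proteins, chlorophyll synthesis, cytosolic ribosomal proteins, histones, cyclins and DNA replication, cell wall loosening and cellulose, proteasome subunits, autophagy proteins and mitochondrial alternative respiration. Root markers, seed storage markers and transposon-related sequences served as checks of tissue and background. Wrong matches, such as a cyclin-dependent kinase among the cyclins, were taken out and missed names added after the annotation could be read. The main list tests used these corrected lists. Running the lists as first written as an alternative was decided after seeing the data.

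Named genes followed a rule. For each stress comparison and for the difference it took the 10 largest rises and falls among called genes, and 5 each way for the type comparisons. These genes were above background and unsaturated on every compared array and had an informative annotation. In the stress and type comparisons their arrays also did not overlap between groups, which was not asked for the difference. To these it added up to 3 genes per direction seen above background in 1 group alone, the 3 members of each list with the smallest p, and 20 genes of stress biology fixed by locus, of which NCED3 was not on the array and bZIP23 carried an annotation that did not match. The text leaves out part of these genes to stay readable, and all are in the tables. Some genes that the rule took for 1 comparison are given in others as well.

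Alternatives were quantile scaling, normexp background correction (offset 50) with quantile scaling, no filter, a stricter filter (above background on all 8 arrays, 22084 genes), the deposited value table, a fit of the compared arrays alone, the replicate number as a block, each array left out in turn, the mean of a gene's probes, an intensity trend in the variance prior, and a call that also asked for a 2-fold change. Replicate numbers do not pair the arrays: residuals of arrays with the same number correlated between −0.0639 and 0.1102. With that block 3059 genes rose and 3799 fell in the high type, 5270 rose and 3367 fell in the low type, and 1667 and 2893 differed in response.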

Results

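Transcript levels were measured in whole rice seedlings with 1-colour Agilent arrays. AC39020, which the labels call the high type, and BPT5204, the low type, had been selected on their responses to stress. Each type was profiled under control conditions and under stress, with 2 arrays in each of the 4 groups. The labels name neither the kind of stress nor its length. The 75th percentile of the processed signal ran from 1462.9 to 1825.9 intensity units on the high-type arrays and from 1476.5 to 1536.6 on the low-type control arrays. It was 806.9 and 1146.5 on the low-type stress arrays, which were the dimmest. Between 67.7% and 74.4% of probes per array lay well above background, and the number of arrays limits the precision. Of 38028 genes on the array, 27329 were tested. The first component of all tested genes held 64.9% of the variance and parted the types, and the second held 19.4% and parted stress from control.

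Changes are given on the log2 scale relative to the median gene of the same comparison, as value ± standard error of the limma fit (n = 2 arrays per group). Folds of single genes are on the same basis. Counts of genes past a 2-fold change use the change before the median is subtracted. Loci without another name are given by what their annotation says. The words rose and fell are kept for genes past an adjusted p of 0.05, which tests the change before the median is subtracted.

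**Figure D1:**
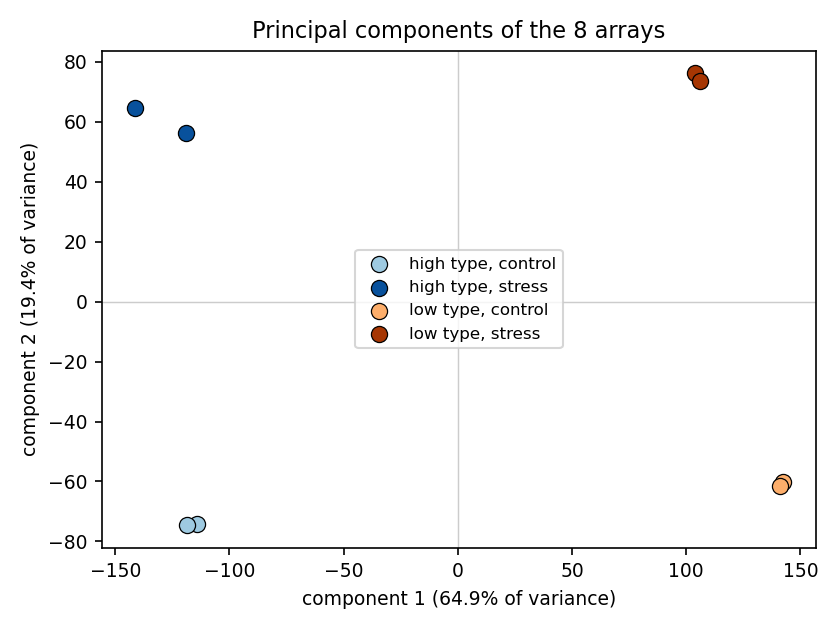
Each point is 1 array, placed by its scores on the first and second principal components of the log2 signal of all tested genes (axes in component units, percent of variance in the axis labels). Types part on the first component and treatments on the second.

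The first comparison addressed which genes respond to stress in the high type. Late embryogenesis abundant (LEA) proteins and dehydrins, hydrophilic proteins that accumulate in drying tissue and ripening seeds, showed the largest shift of the lists. Of 22 tested members 16 rose and 2 fell (16 and 2 adjusted over the list alone), and the median member stood 4.28 above the median gene (adjusted p = 5.80e-11; adjusted p = 0.312 with an estimated correlation). The dehydrin RAB16A (Os11g0454300), a gene induced by abscisic acid, rose 123.7-fold (6.95 ± 0.12, adjusted p = 2.28e-05). LEA3 (Os05g0542500) rose 113.1-fold (6.82 ± 0.12) and a DHN1-like dehydrin (Os11g0451700) rose 104.0-fold (6.70 ± 0.18). A LEA-repeat protein (Os03g0168100) was above background under stress and not in the control, at least 195.6-fold higher. Outside this list a SIGE-like sigma factor of plastid RNA polymerase (Os05g0586600) rose 200.1-fold (7.64 ± 0.17) and an early light-inducible protein (ELIP, Os07g0178800), a thylakoid protein of stressed plastids, rose 196.0-fold (7.62 ± 0.53). An MtN3-family protein (Os02g0513100) rose 95.8-fold (6.58 ± 0.18) and an HSP70 chaperone (Os03g0277300) 92.4-fold (6.53 ± 0.23). A cytosolic NADP malic enzyme (Os01g0743500) was at least 51.1-fold higher under stress than the background level of the control.

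Genes of jasmonate synthesis and JAZ repressors moved down in the high type. Of 39 tested 18 fell and 2 rose (21 and 3 adjusted over the list alone), with a median of −0.67 (adjusted p = 7.13e-04; adjusted p = 0.415 with an estimated correlation). A lipoxygenase (Os10g0361000) fell by 6.95 ± 0.15 (adjusted p = 2.28e-05), and the chloroplast lipoxygenase Os08g0508800 fell by 3.85 ± 0.12. WRKY transcription factors, many of them regulators of defence, had 33 members that fell and 4 that rose of 65 (35 and 7 adjusted over the list alone), with a median of −0.86 (adjusted p = 1.64e-04; adjusted p = 0.441 with an estimated correlation). WRKY76 (Os09g0417600) fell by 4.64 ± 0.30 and WRKY62 (Os09g0417800) by 3.56. Of 141 cytosolic ribosomal proteins 45 fell and 1 rose (55 and 1 adjusted over the list alone), mostly by small amounts, with a median of −0.34 (adjusted p = 5.80e-11; adjusted p = 0.618 with an estimated correlation). L31 (Os08g0505300) fell by 0.96 and L34 (Os08g0156800) by 0.82. Cyclins and DNA replication proteins, which serve dividing cells, had 11 falls and 0 rises among 29 (13 and 0 adjusted over the list alone), with a median of −0.45 (adjusted p = 8.24e-03; adjusted p = 0.618 with an estimated correlation). The median was −0.22 without high-type stress replicate 2 and −0.28 under normexp with quantile scaling, and in both the call stayed at the preset correlation. An MCM4-like subunit of the replicative helicase (Os01g0544450) fell by 1.29 ± 0.13, and MCM10 (Os09g0539400) fell by 1.16, a call that normexp with quantile scaling ended (adjusted p = 1.23e-01). Class III peroxidases of the cell wall had 12 falls and 3 rises among 47 (12 and 3 adjusted over the list alone), with a median of −0.50 (adjusted p = 2.53e-02; adjusted p = 0.618 with an estimated correlation), and Os06g0546500 fell by 2.89 while Os07g0639000 rose by 1.86. Without high-type stress replicate 1 the adjusted p of the peroxidases was 4.96e-01. PR1a (Os07g0129300), a defence marker, fell by 5.40 ± 0.19 and a β-tubulin (Os06g0671600) by 5.33 ± 0.10.

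Antioxidant enzymes had 7 rises and 2 falls among 42 in the high type (7 and 2 adjusted over the list alone), with a median of 0.39 (adjusted p = 1.16e-02; adjusted p = 0.637 with an estimated correlation). A 1-Cys peroxiredoxin (Os07g0638300) rose by 2.10 ± 0.24, and a dehydroascorbate reductase (Os05g0116100), which recycles ascorbate, rose by 1.48, a call lost without either high-type control array (highest adjusted p = 5.57e-02). The member with the smallest p fell by 1.47 (Os01g0284500) and is a nectarin-like protein listed through its superoxide dismutase number. CATB (Os06g0727200) rose by 0.72 ± 0.13, a call lost when only the compared arrays were fitted or when either high-type control array was left out (highest adjusted p = 9.28e-02), and CATA (Os02g0115700) at −0.27, CATC (Os03g0131200) at 0.98, APX1 (Os03g0285700) at 0.02 and APX2 (Os07g0694700) at 0.62 were not called. Autophagy proteins had 6 rises and 0 falls among 13 (6 and 1 adjusted over the list alone), with a median of 0.71 (adjusted p = 1.02e-03; adjusted p = 0.441 with an estimated correlation). ATG13 (Os04g0538700) rose by 1.19 ± 0.11 and ATG7 (Os01g0614900), an activating enzyme of the conjugation step, by 1.47. Mitochondrial alternative respiration had 5 rises and 1 fall among 9 (5 and 1 adjusted over the list alone), with a median of 0.58, and alternative oxidases AOX1a (Os04g0600200), AOX1b (Os04g0600300) and AOX1c (Os02g0700400) rose by 1.48, 1.55 and 1.67. The call of this list was marginal (adjusted p = 4.81e-02; adjusted p = 0.441 with an estimated correlation), and it was lost without either high-type stress array or any 1 of the 4 low-type arrays (highest adjusted p = 9.59e-02), and with the stricter filter, the mean of probes, the compared arrays alone or the replicate number as a block (highest adjusted p = 8.88e-02).

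The other lists were not called in the high type. Heat stress transcription factors had 8 rises and 3 falls among 19, small heat shock proteins 7 and 4 of 25, and HSP70, HSP90, HSP100 and HSP40 chaperones 23 and 11 of 136. HSP101 (Os05g0519700), matched into the small heat shock list, rose by 3.43 ± 0.13, and a class II small heat shock protein (Os02g0782500) by 5.87. Protein phosphatases 2C, the family of the abscisic acid co-receptors, had 11 rises and 8 falls among 46, and Os05g0572700 rose by 5.77. Osmolyte synthesis had 3 rises and 5 falls among 21, and a pyrroline-5-carboxylate synthase (P5CS, Os01g0848200), which makes proline, rose by 3.51 ± 0.12. The list of abscisic acid synthesis and breakdown held 1 tested gene, too few for a test. It was a zeaxanthin epoxidase (Os04g0448900), which rose by 1.31, a call lost when only the compared arrays were fitted or without either high-type control array (highest adjusted p = 1.22e-01). Rises and falls were 10 and 14 of 54 glutathione S-transferases, 18 and 16 of 93 thioredoxins and glutaredoxins, 7 and 4 of 51 proteins of aldehyde and carbonyl detoxification, and 0 and 0 of 5 respiratory burst oxidases. Among regulators they were 8 and 13 of 64 AP2/ERF and DREB factors, 6 and 10 of 41 NAC factors, 4 and 4 of 27 bZIP factors and 17 and 15 of 94 MYB factors. They were 14 and 31 of 99 defence proteins, 0 and 3 of 6 aquaporins, 5 and 2 of 49 light harvesting and photosystem proteins, 2 and 2 of 12 proteins of chlorophyll synthesis, 5 and 5 of 38 histones, 13 and 11 of 84 proteins of cell wall loosening and cellulose, and 3 and 2 of 37 proteasome subunits. Root markers had 6 rises and 5 falls among 18, seed storage markers 1 and 3 of 14, and transposon-related sequences 2 and 2 of 17. Of the genes named in advance, SALT (Os01g0348900) rose by 1.89 ± 0.26, NAC6 (Os01g0884300) by 1.17 and DREB2A (Os01g0165000) by 1.04, the root marker RCc3 (Os02g0662000) fell by 1.91 ± 0.29, and HSFA2C (Os10g0419300) at −0.09 was not called. DREB1A (Os09g0522200) fell by 2.97 ± 0.79, a call lost without any 1 array of the high-type control or of either low-type group, without the filter and with the compared arrays alone (highest adjusted p = 1.49e-01).

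In total 3498 genes rose and 4310 fell in the high type, 28.6% of those tested, and 1772 and 2414 of them by at least 2-fold. The count was 3173 without control replicate 1 of the high type, where rises outnumbered falls (1684 and 1489), 3735 without its control replicate 2, and 4329 when only the 4 high-type arrays were fitted. Among the tested genes 439 were above background on both stress arrays and neither control array, and 331 the other way round, of which 257 and 205 were called.

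**Figure D2:**
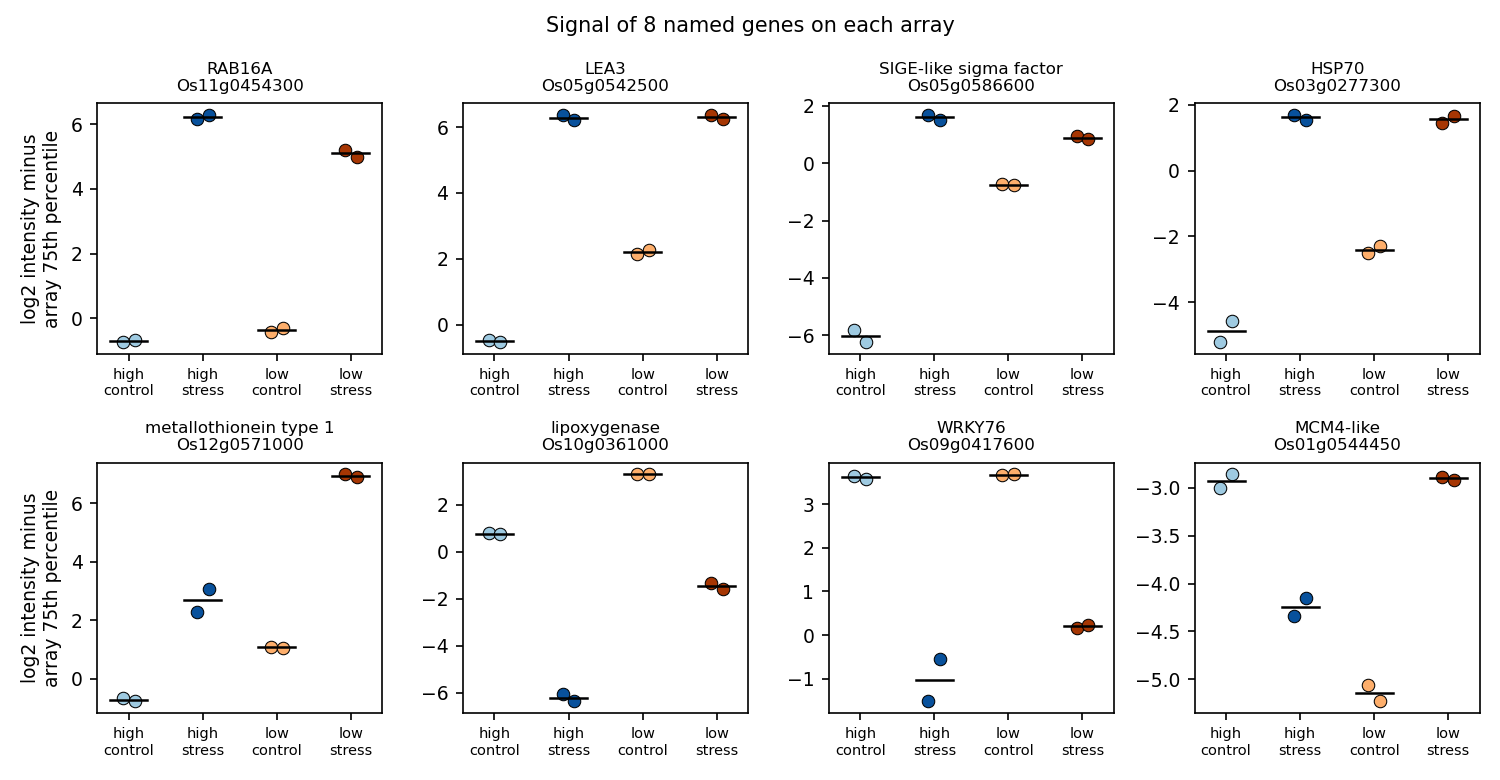
Each point is 1 array and each bar the mean of 2, for 8 named genes in the 4 groups (y axis: log2 intensity minus the 75th percentile of the array, with a scale of its own in each panel). RAB16A, LEA3, the SIGE-like factor, HSP70 and the metallothionein were higher under stress in both types, the lipoxygenase and WRKY76 lower, and the MCM4-like gene fell in the high type and rose in the low type.

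The second comparison addressed which genes respond to stress in the low type. LEA proteins and dehydrins rose there too: 16 of 22 rose and 1 fell (16 and 2 adjusted over the list alone), with a median of 2.97 (adjusted p = 5.48e-07; adjusted p = 0.315 with an estimated correlation). RAB16A (Os11g0454300) rose 39.0-fold (5.28 ± 0.12, adjusted p = 6.44e-05), and RAB16B (Os11g0454200), RAB16D (Os11g0453900) and RAB16C (Os11g0454000), which lie beside it on chromosome 11 by their locus numbers, rose by 5.32 ± 0.13, 5.21 ± 0.19 and 4.69. The MtN3-family gene Os02g0513100 rose 94.5-fold (6.56 ± 0.18). Metallothioneins, small cysteine-rich metal-binding proteins, were among the largest rises: Os12g0571000 rose 52.8-fold (5.72 ± 0.25, adjusted p = 1.36e-04), Os12g0568200 rose by 5.12 ± 0.22, and Os12g0568133 was at least 122.7-fold above the background level of the control. An embryonic abundant protein 1-like gene (Os05g0349800) was at least 72.9-fold higher, and a lectin (Os04g0173800) at least 50.7-fold higher.

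Histones rose in the low type: 21 of 38 rose and 2 fell (22 and 3 adjusted over the list alone), with a median of 0.41 (adjusted p = 6.50e-04; adjusted p = 0.779 with an estimated correlation), or 0.26 without the filter and 0.62 under quantile scaling. Histone H4 (Os03g0119900) rose by 1.73 ± 0.13, H2A (Os05g0113900) by 2.25 ± 0.16 and H3.1 (Os05g0438700) by 2.34 ± 0.19. Cyclins and DNA replication proteins had 13 rises and 1 fall among 29, and as a list they missed the threshold (adjusted p = 1.00e-01). The MCM4-like gene (Os01g0544450) rose by 2.08 ± 0.13 (adjusted p = 2.70e-04), MCM10 (Os09g0539400) by 2.01 and a D-type cyclin (Os12g0588800) by 1.59. Proteins of cell wall loosening and cellulose had 32 rises and 7 falls among 84 and also missed it (adjusted p = 7.49e-02), and the expansin EXPA2 (Os01g0823100) rose by 2.43.

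Jasmonate synthesis and JAZ repressors moved down in the low type, with 21 falls and 1 rise among 39 (21 and 1 adjusted over the list alone) and a median of −0.82 (adjusted p = 1.98e-06; adjusted p = 0.315 with an estimated correlation). Lipoxygenases Os10g0361000, Os08g0508800 and Os08g0509100 fell by 4.92 ± 0.15, 4.51 ± 0.12 and 3.13. WRKY factors had 18 falls and 6 rises among 65 (18 and 6 adjusted over the list alone), with a median of −0.51 (adjusted p = 6.50e-04, and adjusted p = 0.779 with an estimated correlation). WRKY76 (Os09g0417600) fell by 3.64 and another WRKY factor (Os01g0584900) by 2.48. An OsD305-like gene (Os09g0353200) fell by 5.68 ± 0.18 (adjusted p = 7.32e-05) and the β-tubulin Os06g0671600 fell by 5.54 ± 0.10. A C2H2 zinc finger gene (Os07g0590100) was at least 74.9-fold lower. The clock gene late elongated hypocotyl (Os08g0157600), a morning-phased MYB factor, fell by 3.17 ± 0.14 (adjusted p = 1.55e-04). Cytosolic ribosomal proteins had 15 falls and 3 rises among 141 (0 and 1 adjusted over the list alone) and a median of −0.39 (adjusted p = 1.98e-06; adjusted p = 0.884 with an estimated correlation). That call ended under quantile scaling (adjusted p = 4.50e-01) and under normexp with quantile scaling (adjusted p = 4.23e-01), and the members with the smallest p, S9 (Os03g0379500), S13 (Os02g0677800) and S10-1 (Os01g0962600), rose by 0.71, 0.44 and 0.48. The S13 and S10-1 calls were lost without either low-type control array or low-type stress replicate 1, the S10-1 call also without low-type stress replicate 2, and the S13 call also under both quantile scalings (highest adjusted p = 1.66e-01 and 9.64e-02).

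The remaining lists were not called in the low type. Among them, antioxidant enzymes, class III peroxidases, autophagy proteins and alternative respiration had been called in the high type. The test of the difference between the types called none of these in the main setting, so no difference in their response was shown. Antioxidant enzymes had 6 rises and 5 falls among 42, class III peroxidases 6 and 7 of 47, glutathione S-transferases 18 and 7 of 54, thioredoxins and glutaredoxins 20 and 15 of 93, aldehyde and carbonyl detoxification 18 and 8 of 51, and respiratory burst oxidases 1 and 1 of 5. The dehydroascorbate reductase Os05g0116100 rose by 1.43, and CATA, CATB, CATC, APX1 and APX2 were not called. Autophagy proteins had 6 rises and 0 falls among 13 (adjusted p = 1.74e-01) and alternative respiration 4 and 2 of 9, with AOX1a (Os04g0600200) up by 1.21 ± 0.09 and AOX1b (Os04g0600300) by 1.89. Small heat shock proteins had 9 rises and 4 falls among 25, chaperones 22 and 24 of 136, heat stress factors 5 and 6 of 19, protein phosphatases 2C 8 and 8 of 46, and osmolyte synthesis 4 and 2 of 21, with P5CS Os01g0848200 up by 3.72 ± 0.12. Regulators gave 16 rises and 8 falls for AP2/ERF and DREB, 7 and 9 for NAC, 6 and 9 for bZIP and 16 and 14 for MYB factors. Defence proteins had 26 rises and 22 falls, aquaporins 2 and 2, light harvesting and photosystem proteins 4 and 3, chlorophyll synthesis 1 and 3, and proteasome subunits 3 and 0. Root markers had 4 rises and 3 falls among 18, seed storage markers 1 and 3 of 14, and transposon-related sequences 2 and 2 of 17. SALT (Os01g0348900) rose by 2.21 ± 0.26 and RCc3 (Os02g0662000) fell by 2.15 ± 0.29. DREB2A (Os01g0165000) fell by 0.52, a call lost under both quantile scalings, without the filter, with the mean of probes, with the replicate number as a block and without any 1 control array or low-type stress array (highest adjusted p = 2.23e-01).

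In total 5635 genes rose and 3774 fell in the low type, 34.4% of those tested, and 3044 and 1810 of them by at least 2-fold. The excess of rises depended on the scaling, with 4448 rises and 4002 falls under quantile scaling. The count was 4669 and 4538 without control replicates 1 and 2 and 5749 without stress replicate 1 of the low type. Of the tested genes 542 were above background under stress alone and 456 under control alone, and 441 and 241 of them were called.

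**Figure D3:**
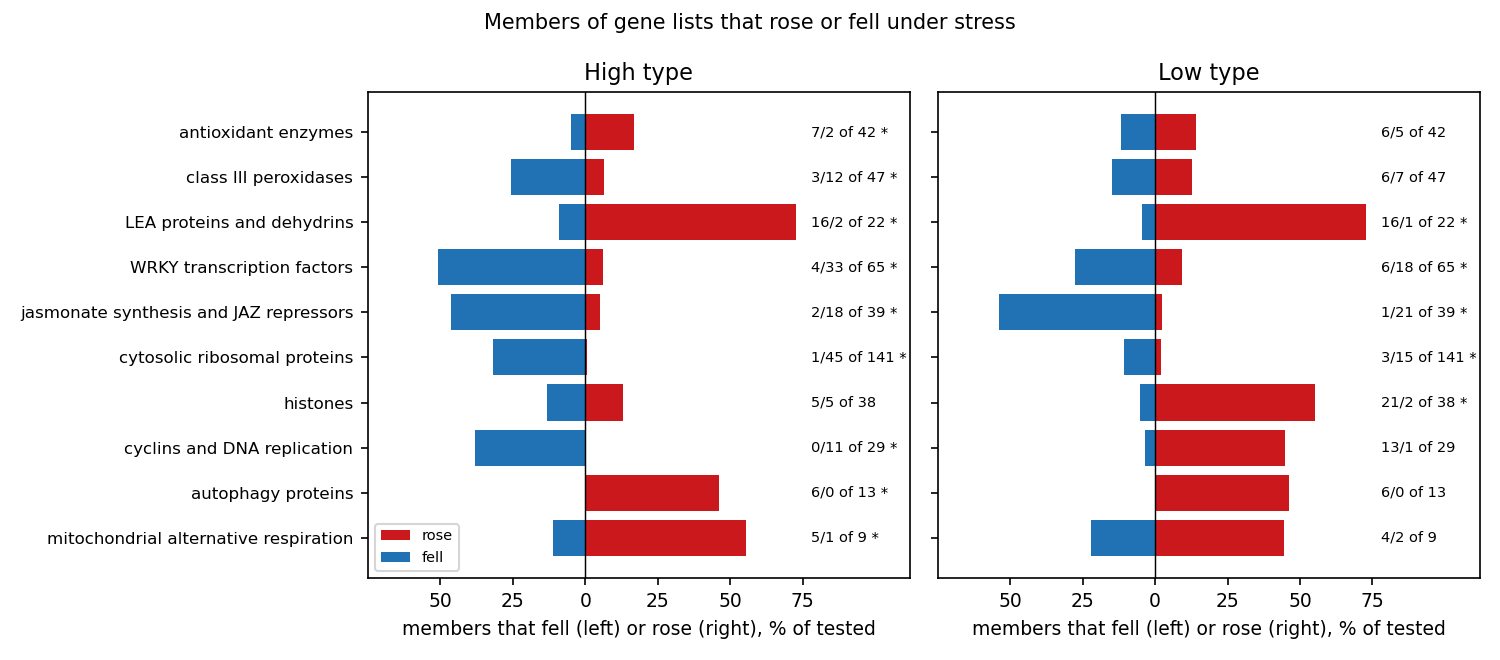
Bars give, for the 10 lists called in at least 1 type, the percent of tested members that rose (to the right) and fell (to the left) under stress, with the counts beside them and asterisks on called lists. LEA proteins and dehydrins had 16 rises among 22 in each type, and the call of cytosolic ribosomal proteins in the low type ended under quantile scaling.

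The responses of the types were compared across all tested genes to ask how far they were shared. Both types had 1721 genes that rose, against 721 for independent calls, and 1792 that fell, against 595. Genes that rose in the high type and fell in the low type numbered 256 (483 for independent calls), and 560 did the reverse (889). The calls of both types rest on the same spread per gene, taken over the arrays of all groups, so they are not independent. A gene with a small spread is more readily called in both types, and the excess over independent calls can overstate the sharing. Such a spread would raise the opposite calls too, and these lay below the figures for independent calls. The MtN3-family gene Os02g0513100, the P5CS gene Os01g0848200 and the β-tubulin Os06g0671600 changed by 6.58, 3.51 and −5.33 in the high type and by 6.56, 3.72 and −5.54 in the low type. Across genes, which are not independent replicates, the changes gave a Pearson r of 0.452 and a Spearman rho of 0.346, with no array used on both sides. The count of 3513 genes called in the same direction was 1747 and 1857 without high-type control replicates 1 and 2, 1885 and 1870 without low-type control replicates 1 and 2, and 5590 and 5802 without high-type stress replicates 1 and 2.

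The third comparison tested the difference itself, the stress change in the high type minus that in the low type, and addressed how the responses of types selected on their stress responses differ. DNA replication genes and histones went apart. Of 29 cyclins and DNA replication proteins 14 had a lower change in the high type and 0 a higher one (14 and 0 adjusted over the list alone), with a median difference of −0.93 (adjusted p = 1.61e-03; adjusted p = 0.630 with an estimated correlation), or −0.41 with the mean of a gene's probes. The MCM4-like gene (Os01g0544450) fell in the high type and rose in the low type, with a difference of −3.42 ± 0.18 (adjusted p = 1.08e-03), and MCM10 (Os09g0539400) differed by −3.21. Among 38 histones 14 had a lower and 3 a higher change in the high type (16 and 3 adjusted over the list alone), with a median of −0.32 (adjusted p = 3.68e-02; adjusted p = 0.734 with an estimated correlation). H2A (Os05g0113900) differed by −3.09 ± 0.23 and H3 (Os04g0419600) by −3.53 ± 0.47. The histone call was lost without high-type control replicate 2, low-type stress replicate 1 or low-type stress replicate 2 (highest adjusted p = 6.77e-02), although the median was −0.31, −0.37 and −0.38 there, and with the lists as first written (adjusted p = 5.61e-02).

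LEA proteins and dehydrins had 7 members with a higher and 5 with a lower change in the high type, of 22 (10 and 5 adjusted over the list alone), and a median difference of 0.60 (adjusted p = 2.09e-02; adjusted p = 0.622 with an estimated correlation). LEA3 (Os05g0542500) differed by 2.85 ± 0.17 and RAB16A (Os11g0454300) by 1.63 ± 0.18. Between the types LEA3 stood at −2.66 ± 0.12 under control conditions and at 0.13 under stress, where it was not called. The call of the list was lost with the stricter filter (adjusted p = 1.30e-01), with the lists as first written and without high-type stress replicate 1 (adjusted p = 9.43e-02). Chaperones of the HSP70, HSP90, HSP100 and HSP40 families had 25 members with a higher and 8 with a lower change, of 136 (25 and 9 adjusted over the list alone; median 0.18; adjusted p = 3.68e-02; adjusted p = 0.822 with an estimated correlation). The RbcX-like chaperonin Os03g0807900, a Rubisco assembly factor by its name, differed by 3.63 ± 0.17 and HSP70 (Os03g0277300) by 2.69 ± 0.33. Heat stress factors had 5 and 3 of 19 (5 and 4 adjusted over the list alone; median 0.42; adjusted p = 3.68e-02; adjusted p = 0.622 with an estimated correlation), with HSF B-2b (Os08g0546800) at 2.59 ± 0.17. Protein phosphatases 2C had 9 and 4 of 46 (12 and 5 adjusted over the list alone; median 0.31; adjusted p = 3.68e-02; adjusted p = 0.622 with an estimated correlation), with Os05g0572700 at 2.13. The chaperone, heat stress factor and phosphatase calls ended under quantile scaling (adjusted p = 8.80e-02, 7.34e-02 and 7.34e-02), under normexp with quantile scaling, with the mean of probes and without low-type control replicate 2 or low-type stress replicate 1, and the chaperone and heat stress factor calls also without high-type stress replicate 1 (highest adjusted p over the left-out arrays = 4.50e-01, 8.28e-02 and 8.41e-02). The heat stress factor call was lost without high-type stress replicate 2 and with the stricter filter as well, and the lists as first written lost all 3 calls. HSP101 (Os05g0519700) differed by 2.80, DREB2A (Os01g0165000) by 1.52 and NAC6 (Os01g0884300) by 1.29. The other lists were not called for the difference, though some had medians further from the median gene than histones. Proteins of cell wall loosening and cellulose had 5 members with a higher and 22 with a lower change (median −0.51, adjusted p = 7.30e-02). Glutathione S-transferases had 6 and 18 (median −0.45, adjusted p = 1.37e-01).

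Among single genes with a higher change in the high type the SIGE-like sigma factor (Os05g0586600) had the largest difference, 6.13 ± 0.24 (adjusted p = 1.08e-03). Next came a cytochrome P450 (Os02g0570500), with 4.63 ± 0.21, and an ent-kaurene synthase-like gene (Os12g0491800), with 4.58 ± 0.26, a family whose members make diterpene precursors of gibberellins and phytoalexins. The ELIP genes Os01g0246400 and Os07g0178800 differed by 4.22 ± 0.40 and 4.09 ± 0.75. Late elongated hypocotyl (Os08g0157600) differed by 3.09 ± 0.19. On the other side stood a D-arabinono-lactone oxidase (Os08g0519100), with −6.25 ± 1.13, an armadillo-repeat protein (Os12g0493900), with −4.52 ± 0.94, a subtilisin-like protease (Os04g0127100), with −4.36 ± 0.20, and a defensin (Os02g0629800), with −3.78 ± 0.59. The calls of Os07g0178800, Os08g0519100 and Os12g0493900 were lost without any 1 control array of either type, those of Os07g0178800 and Os12g0493900 also without low-type stress replicate 1, and that of Os12g0493900 also without low-type stress replicate 2 (highest adjusted p = 7.54e-02, 6.51e-02 and 8.44e-02). In total 2134 genes had a higher and 3442 a lower change in the high type, 20.4% of those tested, and 816 of these 5576 were called in opposite directions in the types. The size of this excess depended on the scaling, with 2364 higher and 2708 lower under quantile scaling and 2755 and 3052 under normexp with quantile scaling. The total was 1934 and 2406 without high-type control replicates 1 and 2, 10208 and 9729 without high-type stress replicates 1 and 2, 2343 and 2125 without low-type control replicates 1 and 2, and 3514 without low-type stress replicate 1.

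**Figure D4:**
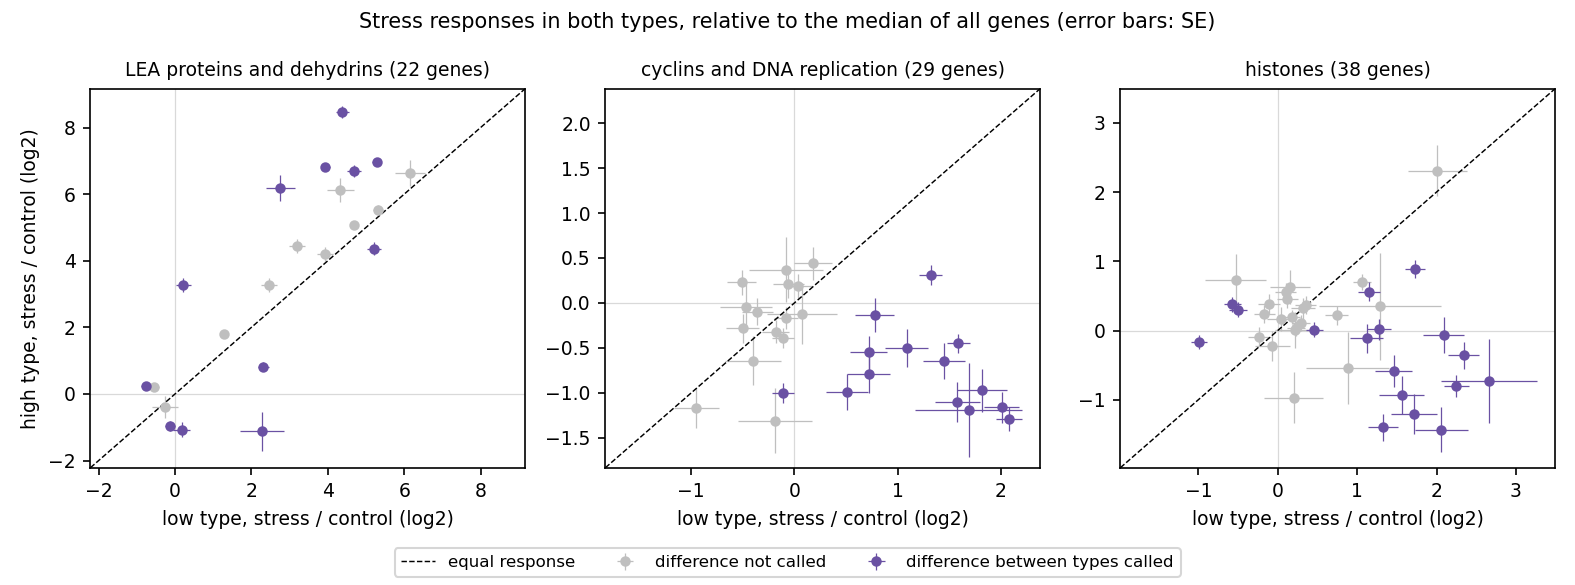
Each point is a gene of the list named above the panel, placed by its stress change in the low type and in the high type (log2, relative to the median gene, bars for the standard error from 2 arrays per group). Coloured points passed the test of the difference between types. DNA replication genes and histones lie mostly below the line of equal response. Of the 22 LEA genes 7 passed with a higher and 5 with a lower change in the high type.

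The last comparisons addressed how the types differ from each other, under control conditions and under stress, as high type over low type. Under control conditions glutathione S-transferases, which conjugate glutathione to reactive compounds, had 26 members higher and 8 lower in the high type of 54 (27 and 8 adjusted over the list alone), with a median of 0.60 (adjusted p = 1.01e-02; adjusted p = 0.587 with an estimated correlation). Proteins of cell wall loosening and cellulose had 37 higher and 11 lower of 84 (39 and 11 adjusted over the list alone; median 0.75; adjusted p = 1.01e-02; adjusted p = 0.662 with an estimated correlation). Cyclins and DNA replication proteins had 16 higher and 3 lower of 29 (16 and 3 adjusted over the list alone; median 0.70; adjusted p = 1.38e-02; adjusted p = 0.669 with an estimated correlation), a call that ended under quantile scaling (adjusted p = 5.10e-02), and the median was 0.44 under normexp with quantile scaling. The MCM4-like gene (Os01g0544450) was 2.27 higher in the high type under control conditions and stood at −1.20 under stress. Under stress glutathione S-transferases again had more members higher, 25 against 9 of 54 (26 and 10 adjusted over the list alone; median 0.46; adjusted p = 2.52e-02; adjusted p = 0.979 with an estimated correlation), a call lost without high-type stress replicate 2 (adjusted p = 6.39e-02) and with the compared arrays alone (adjusted p = 6.91e-02). WRKY factors had 35 members lower and 5 higher of 65 (36 and 5 adjusted over the list alone; median −0.66; adjusted p = 3.91e-02; adjusted p = 0.979 with an estimated correlation), a call lost without low-type stress replicate 2 (adjusted p = 1.53e-01), without the filter, with the mean of probes and with the compared arrays alone (highest adjusted p = 1.24e-01). Cytosolic ribosomal proteins had 35 lower and 6 higher of 141 (17 and 5 adjusted over the list alone; median −0.10; adjusted p = 2.52e-02; adjusted p = 0.979 with an estimated correlation), and that call ended under quantile scaling (adjusted p = 8.65e-02), under normexp with quantile scaling, without the filter, with the compared arrays alone and without replicate 2 of either stress group (highest adjusted p = 2.37e-01).

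A GRF zinc finger gene (Os11g0256300) was 418.6-fold higher in the high type under control conditions (8.71 ± 0.31, adjusted p = 1.28e-05) and 200.8-fold higher under stress. An NTL1 nitrate transporter-like gene (Os06g0581000) stood at −8.37 ± 0.10 (adjusted p = 1.11e-06) under control conditions and at −9.13 ± 0.10 under stress, and a Clp-family gene (Os12g0230100) at −7.86 ± 0.14 and −7.36. A metallothionein 3B gene (Os05g0202800) was 6.47 ± 0.25 higher under control conditions and 3.78 under stress, and a cinnamyl-alcohol dehydrogenase (Os09g0400300) of the lignin pathway stood at −6.03 and −6.78 ± 0.20. The ent-kaurene synthase-like gene (Os12g0491800) stood at −7.41 ± 0.18 under control conditions and −2.89 under stress. Against background in the other type, a chitinase-like gene (Os10g0542900) was at least 525.3-fold higher and an RNase H fold gene (Os01g0944200) at least 1510.2-fold higher in the high type under control conditions. A MADS56-like gene (Os10g0536100) was at least 2953.8-fold lower and a thaumatin-like gene (Os12g0629700) at least 641.3-fold lower. A monosaccharide transporter (Os07g0131600) was at least 370.6-fold lower under stress.

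Under control conditions 6479 genes were higher and 6055 lower in the high type, 45.9% of those tested, and under stress 4882 were higher and 7139 lower, 44.0%. These balances depended on the settings: quantile scaling gave 6271 higher and 6384 lower under control conditions and 5401 and 6450 under stress, where the compared arrays alone gave 2658 and 3049 and a fit without the filter 4488 and 10330. In the main setting 7107 genes differed by at least 2-fold under control conditions (4297 higher and 2810 lower) and 6710 under stress (2756 higher and 3954 lower). Genes higher in both conditions numbered 3191, genes lower in both 3304, and 1029 changed sides. Under control conditions 1938 genes were above background in the high type alone and 557 in the low type alone, and under stress 1727 and 420. Of these, 1479 and 500 were called under control conditions and 1143 and 407 under stress. The bound was over 2-fold for 965 and 512 under control conditions and for 715 and 420 under stress. Fewer probes lay well above background on low-type arrays (67.7% to 69.7%) than on high-type arrays (72.2% to 74.4%). Detection in 1 type alone is thus not by itself a difference in level. The control count was 7884 and 7582 without high-type control replicates 1 and 2 and 7819 and 7960 without low-type control replicates 1 and 2, and the stress count was 7537 without low-type stress replicate 1 and 5707 with the compared arrays alone. The types occupied different slide rows, and control and stress different columns, so row and type, and column and treatment, cannot be told apart.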

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

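None of the tests in this part was chosen after its own result had been seen, but the patterns they address were noticed in these data. Most values stand here because the stress change differed between the types in a direct test of the difference. Such a difference was found for 5576 genes, and for 123 of the genes the text's rule took for the stress comparisons.

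DNA replication genes (adjusted p = 1.61e-03; adjusted p = 0.630 with an estimated correlation) and histones (adjusted p = 3.68e-02; adjusted p = 0.734 with an estimated correlation) had a lower stress change in the high type than in the low type, with median differences of −0.93 and −0.32. Scaling of the dimmer low-type stress arrays was tested by both quantile scalings. The replication list stayed called at the preset correlation (adjusted p = 3.05e-03 and 3.40e-03), with a weakest median of −0.45 (SE 0.18). This SE comes from resampling the genes of the list and does not measure variation between arrays. The median lay beyond −0.2, a cut-off chosen in advance and not derived from data, and only at that cut-off argues against scaling as the whole cause. The size shrank, and the stricter bound of −0.4 was passed by less than its error. With the mean of probes the median was −0.41 (SE 0.41). Quantile scaling does not restore weak signal, so a part played by the dimmer arrays stays open. A single deviating array was argued against for the replication list, whose weakest median without 1 array was −0.63 (without high-type stress replicate 2, SE 0.34 over its genes). The histone median stayed between −0.31 and −0.42 over the same 8 fits, so no single array carried its size. Its SE over the genes of the list was 0.26 in the main fit, close to the median of −0.32. The histone call, near the threshold, was lost without high-type control replicate 2, low-type stress replicate 1 or low-type stress replicate 2 (medians −0.31, −0.37 and −0.38). Under stress itself neither list was called between the types (replication median −0.29, adjusted p = 4.20e-01, histone median −0.31, adjusted p = 2.44e-01). Under control conditions the replication list stood higher in the high type (median 0.70, adjusted p = 1.38e-02, and 0.669 with an estimated correlation). Its lower stress change thus goes with control levels too. Slide position cannot be told apart from type and treatment. A difference between the types in how cell division responds to stress is a hypothesis that no measurement here tests.

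Genes with large differences between the types may owe them to sequence variants under single probes, since the array was designed on a reference genome. The test covered 189 genes with several probes whose brightest probe differed at least 8-fold under control conditions. Of 317 other probes of these genes 85.5% differed at least 2-fold the same way. The shares were 91.4% of 81 and 88.4% of 69 for stress changes in the high and the low type. This argues against single-probe variants as the general cause in those 189 genes. Genes with 1 probe, 30119 of the 38028 on the array, could not be tested this way. Missing or diverged segments of the genome would put such genes side by side. Counting pairs with different annotations, genes seen in 1 type alone were neighbours 2.3 times (SE 0.2) as often as at shuffled positions. Taken apart, genes of the high type gave 2.8 (SE 0.3) and genes of the low type 5.1 (SE 1.6). Genes changed at least 8-fold by stress gave 2.2 (SE 0.5) in the high type and 2.5 (SE 0.6) in the low type. Over all neighbouring pairs the ratios of genes seen in 1 type alone were 2.5 (SE 0.2), 3.0 (SE 0.3) and 5.6 (SE 1.6) in the same order. The stress ratios were then 3.1 (SE 0.6) and 3.6 (SE 0.7). In both counts only the ratio of the low type, from 10 and 12 pairs, exceeded both stress values by more than the errors. Over all pairs the ratio of both types together lay below both stress values. Segments and expression cannot be told apart by these counts, and a difference of the types in expression stays open with segments.

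Late elongated hypocotyl (Os08g0157600), a morning clock gene, was highest in the low-type control seedlings and fell by 3.17 in the low type alone, with a difference between types of 3.09. Sampling at another time of day could have raised evening clock genes in the low type, but 1 of 7 (14.3%) rose, an ELF4-like gene (Os11g0621500). GIGANTEA (Os01g0182600) and both TOC1-like genes (Os02g0148500 and Os11g0157600) were not called. Nor was an FKF1-like gene (Os11g0547000), at 0.91 ± 0.46 before the median is subtracted. A count of calls from 2 arrays per group can miss modest rises, so it cannot exclude a smaller shift in sampling time. A LHY-like gene (Os04g0583900) rose by 5.64 and 4.15 in the high and the low type. A response of this gene that depends on the type is a hypothesis found and tested on the same data.

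The differences of heat stress transcription factors, HSP70, HSP90, HSP100 and HSP40 chaperones and protein phosphatases 2C each had an adjusted p of 3.68e-02, and that of LEA proteins and dehydrins 2.09e-02. In that order these lists had an adjusted p = 0.622, 0.822, 0.622 and 0.622 with an estimated correlation, and the first 3 also lost their calls under both quantile scalings. Among single genes the difference was 6.13 for the SIGE-like gene Os05g0586600, 4.63 for the cytochrome P450 Os02g0570500, 4.58 for the ent-kaurene synthase-like Os12g0491800, and 4.22 and 4.09 for the ELIP genes Os01g0246400 and Os07g0178800. It was 3.97 for an RCC1-repeat gene (Os01g0846800), 3.96 for an amino acid transporter (Os04g0460300), 3.96 for a 4-coumarate ligase (Os02g0697400), 3.92 for an NAD(P)-binding protein (Os02g0137700) and 3.85 for a homeodomain-like gene (Os06g0728700). On the lower side it was −6.25 for the D-arabinono-lactone oxidase Os08g0519100, −4.52 for the armadillo-repeat gene Os12g0493900, −4.36 for the subtilisin-like Os04g0127100, −3.96 for an aquaporin like PIP2-6 (Os07g0448400) and −3.96 for a CEL5-like gene (Os02g0123700). It was −3.89 for an ATL1R-like gene (Os09g0535500), −3.78 for the defensin Os02g0629800, −3.70 for an amino acid transporter (Os01g0597600), −3.59 for a RING finger gene (Os01g0972000) and −3.53 for histone H3 (Os04g0419600). The calls of Os07g0448400, Os09g0535500, Os01g0597600 and Os01g0972000 were lost without any 1 control array of either type (highest adjusted p = 1.37e-01, 1.40e-01, 1.19e-01 and 1.00e-01), the last 3 also without either low-type stress array and the first also without high-type stress replicate 2. Those of Os07g0448400 and Os09g0535500 were lost under quantile scaling too, those of Os07g0448400, Os09g0535500 and Os01g0597600 without the filter, and that of Os09g0535500 with the replicate number as a block.

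Probes without a single rice locus took no part in the gene comparisons, and 1278 of 4374 tested changed under stress in the high type (600 rose and 678 fell) and 1334 in the low type (825 rose and 509 fell).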

How the results depend on the processing

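The lists as first written were fixed before the data were examined. The main list tests used lists corrected after the annotation could be read. Running the first lists as an alternative was decided after seeing the data, and the other alternatives were planned. The deposited value table, the trend, the block and the compared arrays alone leave the change of a gene nearly as it is. So does leaving out an array of a group not compared. Many named genes were chosen in the main fit for large changes or small p, so few reversals could arise. Of 4857 values of named genes under the alternatives, 4699 kept their direction and call, 158 lost the call (114 of them on leaving out 1 array) and 0 reversed, and of 803 values of 48 uncalled gene comparisons 65 became called and 2 reversed: CATB (Os06g0727200) in the low type was 0.31 under normexp with quantile scaling, and SALT (Os01g0348900) between the types under stress was 1.1 with the mean of probes; the cause was not tested. Counts of changed genes stayed within 1.5 times under both scalings, both filters, the deposited value table (7791, 9401, 5567, 12527 and 12008) and the block, and with the compared arrays alone, where 4 arrays estimate the spread, they were 4329 (stress in the high type) and 5707 (types under stress). Asking for a 2-fold change left 4186, 4854, 7107 and 6710 genes in the comparisons within types and between types. Without 1 array the counts ran from 3173 to 11275 (high type), 4538 to 13681 (low type), 1934 to 10208 (difference), 7582 to 16463 (types under control), 7537 to 15172 (types under stress) and 1747 to 5802 (same direction in both types); the lone array left in a group is assumed to vary like the others, and counts were highest without a high-type stress array, the group with the largest spread. The correlation of the types' responses was 0.486 under normexp with quantile scaling, 0.386 without the filter and 0.483 with the stricter filter, and ran from 0.399 (without high-type stress replicate 1) to 0.456 without 1 array; the cause was not tested. Called lists numbered 0 in all 5 comparisons with an estimated correlation. For the difference they were 10 without the filter, 3 with the mean of probes, 1 with the lists as first written and 2 (without low-type stress replicate 1) to 13 (without high-type stress replicate 2) leaving out 1 array, with 3 without low-type control replicate 2. For the types they were 5 under control conditions with normexp and quantile scaling, and under stress 0 with the compared arrays alone and 1 to 6 without 1 array (low-type stress replicate 2 and high-type stress replicate 2); the cause was not tested. A slide block was not run, since there was 1 slide. Signal over background was lowest on the low-type stress arrays (41.9 and 57.1), which limits dim genes there most.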

Other observations

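All tests in this part were chosen only after the data had been seen: 13 further gene lists, 8 of which held named genes. Metallothioneins, which bind metals and scavenge radicals, were picked because members were among the largest rises, so a test of the whole list partly restates that. In the low type 10 of 13 rose and 0 fell, with a median of 2.43 (adjusted p = 5.72e-07; adjusted p = 0.101 with an estimated correlation), and in the high type 8 rose and 1 fell, with a median of 1.08 (adjusted p = 3.29e-03; adjusted p = 0.387 with an estimated correlation). Their stress change was lower in the high type for 9 members and higher for 1, with a median difference of −1.44 (adjusted p = 1.17e-03; adjusted p = 0.156 with an estimated correlation), and under stress 10 stood lower and 1 higher in the high type (median −0.86; adjusted p = 1.13e-02; adjusted p = 0.515 with an estimated correlation). Without the 4 named members 6 of 9 rose and 0 fell in the low type (adjusted p = 1.98e-04; adjusted p = 0.168 with an estimated correlation), and 5 rose and 1 fell in the high type (median 0.98; adjusted p = 1.49e-02; adjusted p = 0.374 with an estimated correlation). The difference between the types was not called without them (median −0.77; adjusted p = 8.41e-02), and under stress 7 of the 9 stood lower and 0 higher in the high type (median −0.84; adjusted p = 1.81e-02; adjusted p = 0.644 with an estimated correlation). The named gene Os12g0571000 rose by 3.43 ± 0.25 in the high type and by 5.72 ± 0.25 in the low type.

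Calmodulins and calcium-binding EF-hand proteins, the sensors of calcium signals and a list without named genes, had 45 falls and 13 rises among 124 in the high type (median −0.33; adjusted p = 1.54e-02; adjusted p = 0.476 with an estimated correlation) and 35 falls and 14 rises in the low type (median −0.45; adjusted p = 4.25e-04; adjusted p = 0.145 with an estimated correlation). Receptor-like kinases of the cell surface had 18 falls and 4 rises among 48 in the high type (median −0.41; adjusted p = 1.16e-02; adjusted p = 0.504 with an estimated correlation) and 20 falls and 9 rises in the low type (median −0.48; adjusted p = 5.53e-03; adjusted p = 0.445 with an estimated correlation), and without the 1 named member both calls stayed (adjusted p = 1.49e-02 and 9.59e-03; adjusted p = 0.463 and 0.439 with an estimated correlation). Terpene synthases had 5 falls and 0 rises among 9 in the low type (median −1.58; adjusted p = 5.53e-03; adjusted p = 0.182 with an estimated correlation) and 4 falls and 1 rise in the high type, where they were not called (adjusted p = 1.29e-01). The 1 rise was the named ent-kaurene synthase-like gene Os12g0491800, and without it the adjusted p was 2.57e-02 in the low type and 1.49e-02 in the high type (adjusted p = 0.263 and 0.374 with an estimated correlation). Not called in either type were kinesins (rises and falls 4 and 7 of 33 in the high type, 12 and 1 in the low type), cytochrome P450 proteins (42 and 42, 46 and 53, of 188), RING zinc finger proteins (40 and 43, 55 and 57, of 286), ABC transporters (10 and 9, 13 and 11, of 54), lipid transfer proteins (12 and 10, 13 and 5, of 43), germin-like proteins (4 and 8, 5 and 6, of 25), subtilisin-like proteases (2 and 5, 5 and 1, of 25), tubulins (4 and 2, 8 and 3, of 20) and MtN3-family sugar transporters (5 and 2, 5 and 3, of 10).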
